A study of Rattus norvegicus with 60 samples.

How the data were processed

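The study profiled RNA from the inside of the knee and from popliteal nodes of 20 rats with haemophilia A on 60 Affymetrix rat gene arrays, 29 of knees and 31 of nodes, with 1 array per sample. Groups, sides and rats were taken from the sample labels, which gave 3 groups per tissue: bled side, contralateral side and sham. The deposited values were log2 expression values made by RMA in Affymetrix Expression Console 1.4.46, per the submitters' processing notes. They ranged from 1.62 to 14.03 with 2 decimals for 36685 probe sets, and no column repeated another. Whether both tissues were normalized together, the options of RMA, and the hybridization batch or scan date of each array were not given in the sources used here. The depth of an array is fixed by its design, so the precision rested on the number of arrays per group, 7 to 11.

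Gene symbols came from the array's annotation, which listed 19086 probe sets, 18511 with 1 symbol and 575 with several; the latter and 17599 unlisted probe sets were tested but not named. For each of 18166 genes the probe set with the highest mean stood for the gene in the list tests. No coordinates were used.

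All computations on the log2 values were made with R 4.3.3 and limma 3.58.1, the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Within each tissue a linear model with the 3 groups was fitted to all probe sets without filter, with moderated t tests and Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. Fold changes are differences of group means of log2 values, given ± SE with 95% intervals where stated, and counts of larger changes used a 2-fold minimum. The 6 comparisons within a tissue set the bled against the contralateral side and each of these against sham. Differences between the tissues were tested as contrasts of contrasts in a model of all 60 arrays.

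Gene lists, 36 with 895 entries and at least 5 measured members each, were written before the data were examined, as were the groups, the comparisons, the tests and most alternative fits. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list and with fry. Members were counted by their adjusted p over all probe sets and adjusted over the list alone. Named genes followed a rule: the 10 largest called changes each way, up to 4 members per list, 7 genes given in every comparison (Il1b, Il6, Tnf, Ccl2, Hmox1, Arg1 and Mmp3), and 6 genes each way for the differences between tissues, ranked among genes with a group mean above the median of the tissue. Genes of the circadian clock were not among the lists fixed in advance.

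The sides of a bled rat come from the same animal, per the labels, so rat pairs the bled and contralateral samples. Deviations from the group means correlated between the sides of a rat from −0.1 to 0.21 in the knee (mean 0.07) and from 0.12 to 0.32 in the node (mean 0.23), and limma's duplicateCorrelation gave 0.078 and 0.266. The models reported had no block, and blocked fits were run as alternatives. Other alternatives set beforehand were fitting only the compared groups, quantile normalization within a tissue, centring each array on its median, leaving out dim probe sets by their mean, an intensity trend with a robust prior, array weights, and 1 probe set per gene. Leaving out the sham arrays that stood apart (knee C5, nodes C2 and C9), leaving out each array in turn, and using the mean of the skeletal muscle genes (knee) or of the adipocyte genes (node) as a covariate were added after the data had been seen. The models were tested on simulated values with the real means and spreads and 200 changed probe sets. No array was left out of the reported fits.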

Results

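Gene expression was measured in rats with haemophilia A, a bleeding disorder in which coagulation factor VIII is lacking. Knee joint tissue and the popliteal lymph node, which drains the lower hind limb, were taken 24 h after a bleed had been induced in 1 knee of 11 rats, or after 9 other rats had undergone a sham procedure. Each bled rat gave tissue from the bled knee, the contralateral knee and the node of each side, so these 4 groups held 11 arrays each. The sham rats gave 9 node arrays and 7 knee arrays, since the other two knees yielded too little RNA. The bled knee and the node of its side were always the left and the contralateral and sham samples the right, so every comparison with the bled side also compared left with right. The bled and the sham rats were separate animals, whereas both sides and both tissues of a bled rat came from the same animal. The number of arrays limited the precision.

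The deposited log2 values had array medians between 5.64 and 5.94. In the knee the first principal component held 56.1% of the variance and placed the bled knees (36.3 to 69) apart from the contralateral (−40.6 to −14.9) and the sham knees (−46.2 to −30.3). The first component of the nodes held 19% of the variance, and the scores of their 3 groups overlapped. The sham knee array of rat C5 correlated less with the rest of its group (0.965) than the next array (0.984), as did the sham node arrays of rats C9 (0.966) and C2 (0.984), the next being at 0.993.

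The side-to-side comparison of the knees asked how the joint in which a bleed had been induced differed from the other knee. The labels call the bled knee injured, so the effects of the injury and of the blood cannot be told apart. Arg1 (probe set 17610985), the gene of the arginine-degrading enzyme arginase 1, was 61.5-fold higher in the bled than in the contralateral knee (log2 fold change 5.94 ± 0.16 SE, n = 11 in each group, adjusted p = 6.34e-22), with a 95% interval of 49.2- to 76.9-fold. Il6 (probe set 17788345), the gene of the inflammatory cytokine interleukin 6, was 53.9-fold higher (5.75 ± 0.19, adjusted p = 2.9e-19). The means of Arg1 and Il6 in the contralateral knee (5.22 and 5.05) lay below the median of every array, where background can compress a fold, so these folds and their intervals may be too low. Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 16.3-fold (4.03 ± 0.16), the monocyte-attracting chemokine gene Ccl2 14.5-fold (3.86 ± 0.29), the interleukin gene Il1b 9.14-fold (3.19 ± 0.22) and Mmp3, a matrix metalloproteinase gene, 4.79-fold (2.26 ± 0.32). These 6 genes were higher in the bled knee of all 11 rats. Tnf rose by far less, 1.28-fold (0.36 ± 0.10, adjusted p = 0.00391), and did so in 10 of the 11 rats.

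**Figure D1:**
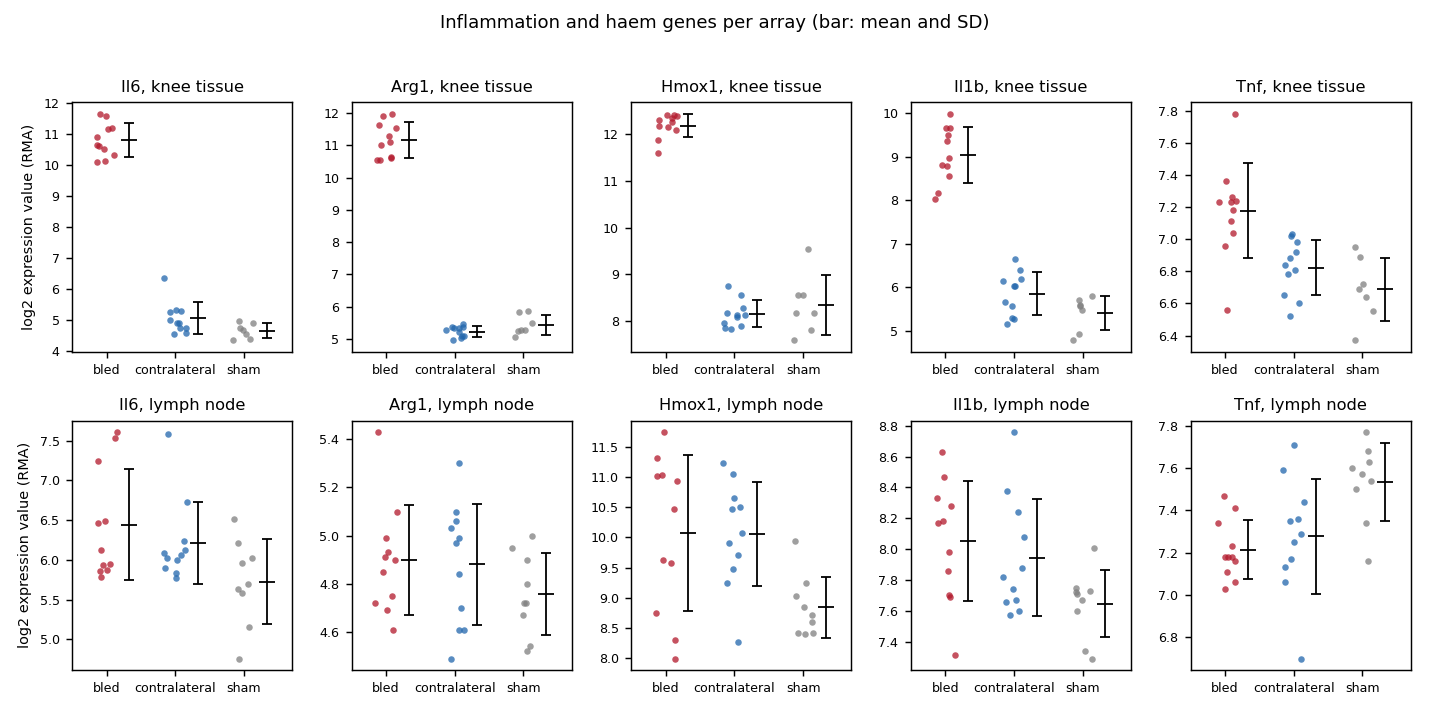
Log2 expression values of Il6, Arg1, Hmox1, Il1b and Tnf in each knee array (upper panels) and lymph node array (lower panels) of the bled side, the contralateral side and the sham rats; each point is 1 array and the bar gives the mean and SD. In the knee the bled side lay between 10.09 and 11.65 for Il6 and between 11.6 and 12.42 for Hmox1, above every contralateral array (highest 6.34 and 8.75), while the node values of the groups overlapped; the value axes differ between panels.

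The other leading increases in the bled knee were in Fgf23, a phosphate-regulating hormone gene (4.96 ± 0.22, 31.2-fold), the collagenase gene Mmp13 (4.60 ± 0.44, 24.2-fold), the lectin receptor gene Clec4a2 (4.54 ± 0.17), the protease inhibitor gene Slpi (4.52 ± 0.25), the chemokine genes Ccl7, Ccl20 and Cxcl2 (4.42, 4.20 and 4.15) and the pentraxin gene Ptx3 (4.13). Of 18 proinflammatory cytokine genes 11 rose and 2 fell, the same counts as when adjusted over the list alone, with Osm at 3.30 and Lif also higher. The proinflammatory cytokine gene list had a camera adjusted p of 0.00301, and adjusted p = 0.256 with an estimated correlation. Of 18 anti-inflammatory and feedback genes 12 rose and 1 fell, among them Il1rn, which encodes the interleukin 1 receptor antagonist (3.67 ± 0.18), and Socs3 (2.39 ± 0.16). The anti-inflammatory and feedback gene list had a camera adjusted p of 7.82e-05, and adjusted p = 0.256 with an estimated correlation. Of 31 chemokine genes 16 rose and 5 fell, or 6 adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.399 with an estimated correlation), and this call was also lost with rat as a block (adjusted p = 0.0814) and without the sham array of C5 (0.0636).

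Several of the leukocyte lists passed in the bled knee and others did not. Of 24 neutrophil markers 17 rose and 2 fell, including the calgranulin genes S100a8 and S100a9 (3.78 ± 0.40 and 3.45 ± 0.38) and the receptor gene Csf3r (3.19 ± 0.17). The neutrophil marker list had a camera adjusted p of 7.82e-05, and adjusted p = 0.399 with an estimated correlation. Of 25 T cell markers 21 rose and 1 fell, with Cd2 at 3.54, Cd8a at 2.06 and the T cell receptor complex gene Cd3g at 1.93. The T cell marker list had a camera adjusted p of 1.21e-06, and adjusted p = 0.256 with an estimated correlation. Of 22 antigen presentation genes 13 rose, or 15 adjusted over the list alone, and 3 fell, with the costimulatory gene Cd80 at 2.79 and Ciita, the activator of class II transcription, at 1.71. The antigen presentation gene list had a camera adjusted p of 0.00617, and adjusted p = 0.399 with an estimated correlation. Of 18 plasma cell and germinal centre genes 10 rose and none fell, including Sdc1 (1.84) and the immunoglobulin joining chain gene Jchain (1.70 ± 0.37). The plasma cell and germinal centre gene list had a camera adjusted p of 0.00536, and adjusted p = 0.256 with an estimated correlation. Of 24 T cell activation genes 11 rose. The T cell activation gene list had a camera adjusted p of 0.019, and adjusted p = 0.399 with an estimated correlation. Monocyte and macrophage markers moved both ways, 14 rising and 8 falling among 25 (15 and 8 adjusted over the list alone), with Spp1 at 3.95 and Cx3cr1 at 2.44 but Vsig4, a complement receptor gene of resident macrophages, at −2.13, and this list did not pass (camera adjusted p = 0.0855). Nor did the B cell markers (7 rising and 4 falling of 18, 8 and 4 adjusted over the list alone, camera adjusted p = 0.264), the NK and cytotoxic cell genes (5 and 1 of 18, 0.681) or the mast cell genes (1 and 4 of 15, 1 and 5 adjusted over the list alone, 0.755).

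Of 18 leukocyte adhesion and trafficking genes 10 rose and 5 fell, with the gene of the adhesion molecule P-selectin, Selp, at 2.74 and the integrin gene Itgam at 2.33. The leukocyte adhesion and trafficking gene list had a camera adjusted p of 0.0414, and adjusted p = 0.399 with an estimated correlation and 0.0536 without the sham array of C5. Of 17 dendritic cell markers 9 rose and 4 fell, with Ly75 at 1.90 and Itgax at 1.88. The dendritic cell marker list had a camera adjusted p of 0.0492, and adjusted p = 0.399 with an estimated correlation, 0.0866 with rat as a block and 0.0651 without the sham array of C5. All 32 cell cycle genes rose, among them Rrm2 (3.27 ± 0.32), the proliferation marker gene Mki67 (2.78 ± 0.36) and Top2a (2.68 ± 0.34); the list had a camera adjusted p of 1.5e-11, and adjusted p = 0.399 with an estimated correlation. Of 29 genes of matrix-degrading enzymes and their inhibitors 16 rose and 7 fell, with Adam8 at 4.06 and the inhibitor gene Timp4 at −2.84. The matrix-degrading enzyme list had a camera adjusted p of 0.0256, and adjusted p = 0.399 with an estimated correlation. Of 20 hypoxia and glycolysis genes 9 rose and 2 fell (3 adjusted over the list alone), with the lactate transporter gene Slc16a3 at 2.10. The hypoxia and glycolysis gene list had a camera adjusted p of 0.019, and adjusted p = 0.475 with an estimated correlation. Of 23 haem and iron handling genes 12 rose, or 13 adjusted over the list alone, and 5 fell, with the metal transporter genes Slc11a1 at 2.68 and Slc39a14 at 2.38, but the list did not pass (camera adjusted p = 0.0803). None of 12 erythroid markers was called, Hba-a1 being at −0.40 ± 0.25 (adjusted p = 0.269) and Slc4a1 at −0.74 ± 0.38 (adjusted p = 0.144).

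Among the genes that fell in the bled knee, Sult1a1, a phenol sulfotransferase gene, was 53.9-fold lower (−5.75 ± 0.24, adjusted p = 1.47e-17) and Omd, which encodes the matrix proteoglycan osteomodulin, 35.7-fold lower (−5.16 ± 0.29). They were followed by Tnfsf10 (−4.50), the galectin gene Lgals12 (−4.34), Cytl1 (−4.30), Myoc (−4.16), Nnat (−3.86), Bche (−3.78), Necab1 (−3.72) and Fmo1 (−3.69). Of 24 adipocyte genes 23 fell and 1 rose, including the leptin gene Lep (−3.54 ± 0.25), Pck1 (−3.28 ± 0.29) and the lipid droplet gene Cidec (−3.19 ± 0.19). The adipocyte gene list had a camera adjusted p of 2.11e-14, and adjusted p = 0.256 with an estimated correlation. Of 23 cartilage matrix genes 10 fell and none rose, with Cilp at −2.98 and Chad at −2.46. The cartilage matrix gene list had a camera adjusted p of 0.00189, and adjusted p = 0.399 with an estimated correlation. Of 27 synovial lining and fibroblast genes 19 fell and 3 rose, with Clic5 at −2.68 and Fap at −1.90 but the hyaluronan synthase gene Has2 at 2.87. The synovial lining and fibroblast gene list had a camera adjusted p of 0.00284, and adjusted p = 0.399 with an estimated correlation. Of 16 complement genes 11 fell, or 12 adjusted over the list alone, and 2 rose, with C6 at −2.27 and Cfd, also an adipocyte product, at −1.84. The complement gene list had a camera adjusted p of 0.000803, and adjusted p = 0.399 with an estimated correlation. Of 24 endothelial and angiogenesis genes 14 fell and 4 rose, with Cd34 at −1.40 and Emcn at −1.39. The endothelial and angiogenesis gene list had a camera adjusted p of 0.0183, and adjusted p = 0.399 with an estimated correlation.

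Interferon-stimulated genes also fell in the bled knee. Of 32 measured, 24 fell and 2 rose (25 and 2 adjusted over the list alone), with the guanylate-binding protein gene Gbp5 at −1.82 ± 0.18, Ifit2 at −1.65 ± 0.16 and Irf7, a regulator of the interferon response, at −1.42 ± 0.27; the camera adjusted p was 3.9e-05, and adjusted p = 0.399 with an estimated correlation. Beside these groups, the mean log2 value of the adipocyte genes was 8.55 ± 0.36 (SD, n = 11) in the bled and 10.65 ± 0.16 in the contralateral knees. Skeletal muscle genes varied widely between arrays, with means from 5.45 to 11.32 in the bled and from 5.67 to 11.52 in the contralateral knees. Among 22 of them only Pygm, the glycogen phosphorylase gene of muscle, was called (−2.09 ± 0.80, adjusted p = 0.0425; 0 adjusted over the list alone); this call was lost when any 1 of 14 arrays was left out or an intensity trend with a robust prior was used.

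**Figure D2:**
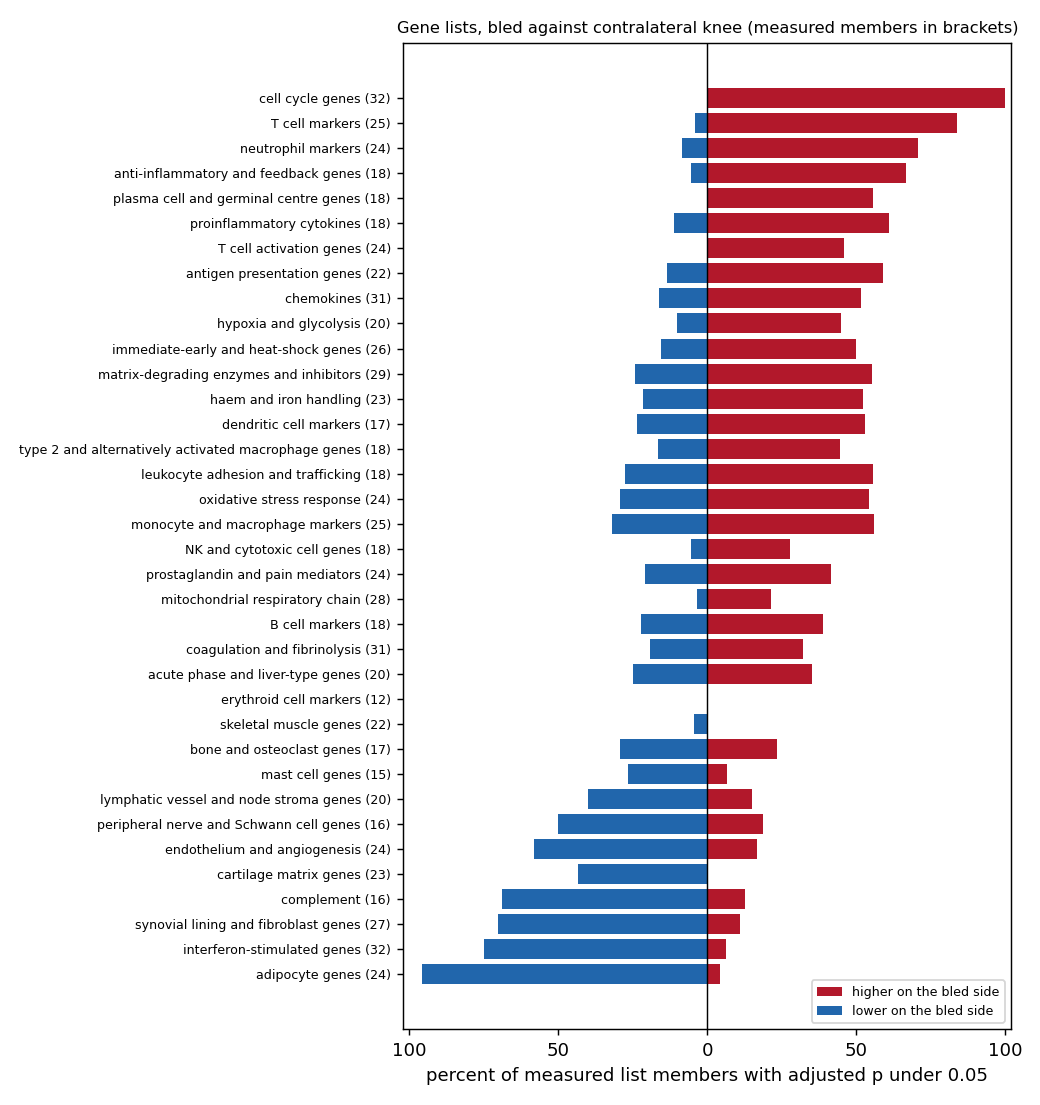
Percent of the measured members of each of the 36 gene lists that were called higher (red, to the right) or lower (blue, to the left) in the bled than in the contralateral knee at an adjusted p under 0.05; the number of measured members stands in brackets. All 32 cell cycle genes were higher and 23 of 24 adipocyte genes were lower.

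In all, 12728 probe sets (34.7%) differed between the bled and the contralateral knee in limma, 7142 higher and 5586 lower, and 1200 were at least 2-fold higher and 1292 at least 2-fold lower. Camera called 19 of the 36 lists, and none of these calls held with an estimated correlation.

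Against the knees of sham rats, the bled knees again showed high Il6, 71.3-fold above sham (6.16 ± 0.22, n = 11 and 7, adjusted p = 1.51e-18), and high Arg1, 53.1-fold above (5.73 ± 0.18). The sham means of Il6 and Arg1 (4.64 and 5.43) also lay below the median of every array, so these folds may be too low. Slpi (5.08 ± 0.29), Mmp13 (4.86 ± 0.50), Clec4a2 (4.78), the osteopontin gene Spp1 (4.75 ± 0.49), Fgf23 (4.75), S100a8 (4.70), S100a9 (4.66) and Ccl7 (4.47) followed. Hmox1 rose 14.3-fold, Ptgs2, which encodes the inducible prostaglandin synthase, 13.2-fold, Il1b 12.5-fold, Ccl2 12.1-fold, Mmp3 7.16-fold and Tnf 1.41-fold (0.49 ± 0.11, adjusted p = 0.000578). The leading decreases were in Sult1a1 (−5.49 ± 0.27, 44.8-fold lower), Omd (−4.56), Lgals12 (−4.50), Tnfsf10 (−4.08), Fndc1 (−3.96), Col6a6 (−3.92), Nnat (−3.91), Bche (−3.91), Pck1 (−3.85) and Myoc (−3.73).

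All 32 cell cycle genes rose against sham (camera adjusted p = 5.35e-11; adjusted p = 0.307 with an estimated correlation), and 23 of 24 adipocyte genes fell, with 1 rising adjusted over the list alone (camera adjusted p = 3.22e-15; adjusted p = 0.153 with an estimated correlation). Of 24 oxidative stress genes 15 rose and 3 fell, including the metallothionein genes Mt1 (2.94 ± 0.20) and Mt2A (2.00 ± 0.18). The oxidative stress gene list had a camera adjusted p of 0.000538, and adjusted p = 0.183 with an estimated correlation. Of 25 monocyte and macrophage markers 15 rose and 7 fell, or 8 adjusted over the list alone. The monocyte and macrophage marker list had a camera adjusted p of 0.00956, and adjusted p = 0.38 with an estimated correlation. Of 23 haem and iron handling genes 13 rose and 5 fell. The haem and iron handling gene list had a camera adjusted p of 0.0184, and adjusted p = 0.38 with an estimated correlation. Of 18 plasma cell and germinal centre genes 11 rose and none fell, or 1 fell adjusted over the list alone, with Jchain at 2.54 ± 0.42. The plasma cell and germinal centre gene list had a camera adjusted p of 0.0105, and adjusted p = 0.183 with an estimated correlation. Of 32 interferon-stimulated genes 19 fell and 3 rose (21 and 3 adjusted over the list alone), with Ifit2 at −1.23 ± 0.18 and Gbp5 at −1.11 ± 0.20 but Ifit1 at 1.57 ± 0.52. The interferon-stimulated gene list had a camera adjusted p of 0.00943, and adjusted p = 0.546 with an estimated correlation.

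Between bled and sham knees 14215 probe sets (38.7%) differed, 7307 higher and 6908 lower, with 1478 at least 2-fold higher and 1319 at least 2-fold lower. With each array centred on its median the split was 8636 higher and 4933 lower. Camera called 23 lists, of which that of the immediate-early and heat-shock genes (12 higher and 4 lower of 26, 13 and 4 adjusted over the list alone, camera adjusted p = 0.0314; adjusted p = 0.546 with an estimated correlation) was lost without the sham array of C5 (adjusted p = 0.0668).

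The contralateral knees were compared with sham knees to ask whether a joint that had not bled differed in a bled rat. The leading increases were in Dbp (2.15 ± 0.19, 4.45-fold, n = 11 and 7, adjusted p = 6.36e-08) and Tef (1.62 ± 0.15, 3.08-fold), genes of related transcription factors with a daily rhythm of expression. Further increases were found in Fmo2 (1.61 ± 0.27), the clock genes Ciart (1.48 ± 0.20), Per3 (1.34 ± 0.16) and Per2 (1.10 ± 0.19), the oxidase gene Nox4 (1.35 ± 0.24), Epm2a (1.31), Adh1c (1.24) and Nat8f3 (1.17). The leading decreases were in Bmal1 (−2.02 ± 0.24, 4.05-fold lower, adjusted p = 1.09e-05), which encodes a core activator of the circadian clock, and in Npas2, another clock gene (−1.82 ± 0.26, 3.53-fold lower). The lipid genes Scd (−1.65 ± 0.30) and Angptl4 (−1.46 ± 0.34) fell as well, followed by Spon2 (−1.32), the collagen genes Col5a3 (−1.27) and Col6a6 (−1.25), Aldh1l2 (−1.25), Arsi (−1.18) and Cit (−1.15).

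**Figure D3:**
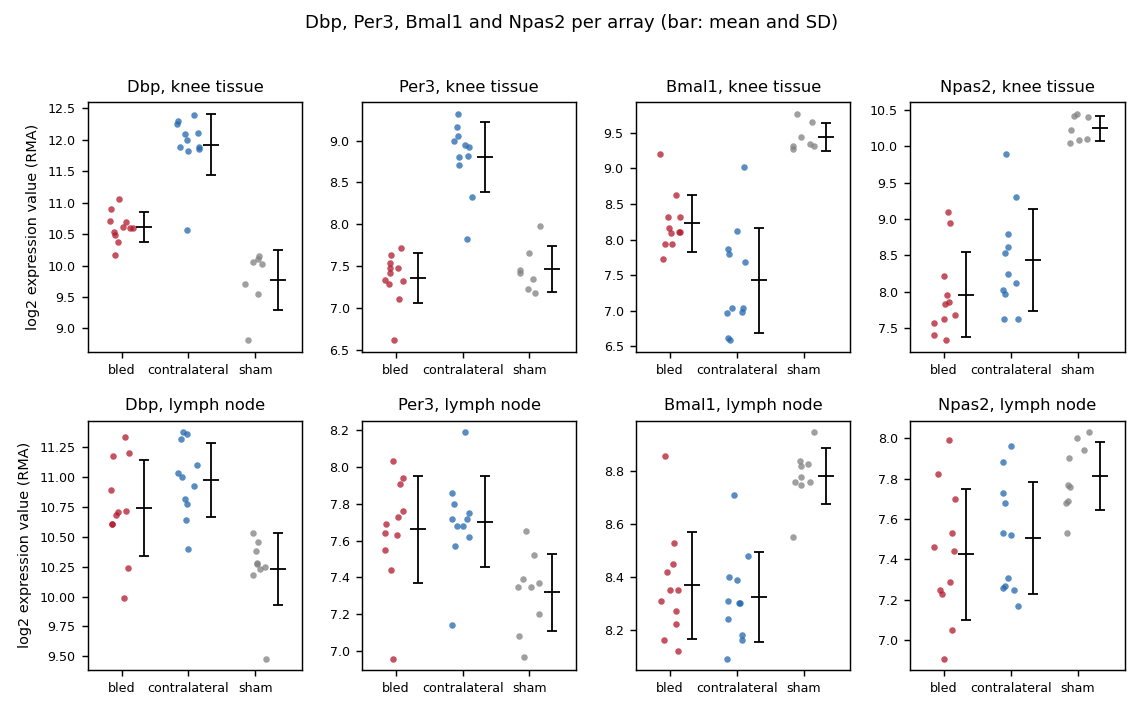
Log2 expression values of Dbp, Per3, Bmal1 and Npas2 in each knee array (upper panels) and lymph node array (lower panels) by group; each point is 1 array and the bar gives the mean and SD. In the knee Bmal1 lay between 9.27 and 9.77 in sham rats and between 6.58 and 9.02 on the contralateral side, and Dbp between 8.81 and 10.15 in sham rats and between 10.57 and 12.4 on the contralateral side; the value axes differ between panels.

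None of the 7 genes followed throughout was called in the contralateral knee. Their log2 differences from sham were 0.58 ± 0.36 for Mmp3, 0.45 ± 0.25 for Il1b, 0.40 ± 0.22 for Il6, 0.13 ± 0.11 for Tnf, −0.19 ± 0.18 for Hmox1, −0.21 ± 0.18 for Arg1 and −0.26 ± 0.33 for Ccl2, with adjusted p from 0.376 to 0.751. Of 24 oxidative stress genes 8 rose, or 13 adjusted over the list alone, and none fell, with Mt2A at 1.09 ± 0.18, Mt1 at 1.05 ± 0.20, Nqo1 at 0.58 ± 0.13 and Gpx3 at 0.51 ± 0.13. This list had a camera adjusted p of 8.69e-09 and was the one called list that held when the correlation was estimated (adjusted p = 0.0259 with an estimated correlation). Of 27 synovial lining and fibroblast genes 7 fell and 1 rose (9 and 2 adjusted over the list alone), with the collagen genes Col5a1 at −0.91 ± 0.12 and Col1a1 at −0.66 ± 0.13 and the matricellular gene Postn at −0.76 ± 0.13. The synovial lining and fibroblast gene list had a camera adjusted p of 0.0053, and adjusted p = 0.491 with an estimated correlation. The aggrecanase gene Adamts4 was also lower (−0.93 ± 0.16).

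Of 22 antigen presentation genes 3 rose, or 4 adjusted over the list alone, including Tap1 (0.52 ± 0.11) and the immunoproteasome gene Psmb9 (0.38 ± 0.09). The antigen presentation gene list had a camera adjusted p of 5.48e-05, and adjusted p = 0.452 with an estimated correlation. Of 25 monocyte and macrophage markers Gpnmb (0.55 ± 0.12) and Mertk (0.42 ± 0.11) rose, and 5 did so adjusted over the list alone. The monocyte and macrophage marker list had a camera adjusted p of 5.48e-05, and adjusted p = 0.452 with an estimated correlation. None of 32 interferon-stimulated genes was called, or 2 adjusted over the list alone, although camera called the list upward (adjusted p = 5.48e-05; adjusted p = 0.491 with an estimated correlation). None of 16 complement genes was called over all probe sets, whereas 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000661; adjusted p = 0.452 with an estimated correlation). Of 18 NK and cytotoxic cell genes 4 rose, among them Prf1 (0.70 ± 0.16), Ccl5 (0.66 ± 0.16) and Gzma (0.50 ± 0.12), and of 26 immediate-early and heat-shock genes 3 rose, namely Ier3 (0.86 ± 0.15), Junb (0.70 ± 0.15) and Zfp36 (0.70 ± 0.12), but neither list passed (camera adjusted p = 0.0966 and 0.0743). Adjusted over the list alone, 5 and 4 members of these lists rose, and 1 immediate-early gene fell. Ptgs2 rose by 0.93 ± 0.24. None of 12 erythroid markers was called, with Slc4a1 at 1.44 ± 0.43 (adjusted p = 0.079) and Hba-a1 at 1.00 ± 0.29 (adjusted p = 0.0677), while 3 were higher adjusted over the list alone and camera called the list (adjusted p = 0.000774; adjusted p = 0.491 with an estimated correlation).

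Between contralateral and sham knees 666 probe sets differed, 361 higher and 305 lower, or 634 and 217 with each array centred on its median. At least 2-fold higher were 23 and at least 2-fold lower 91. The larger share turned to the lower side with array weights (166 higher and 236 lower). It did so too on leaving out the sham array of C5 (169 and 239), C6 (205 and 260) or C9 (235 and 270). In all, 381 were called when only these groups were fitted, 402 with array weights and 408 without C5, of which 339, 375 and 372 were among the 666. Without C5 the calls of Angptl4, Ccl5, Mertk, Nqo1, Gpx3, Ptgs2, Psmb9 and Prf1 were lost. Those of Spon2, Aldh1l2, Tap1 and Gzma were lost in the fit of the compared groups alone and that of Gpnmb with array weights.

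In the popliteal lymph nodes of the bled rats, the side of the bleed was compared with the other side. No probe set was called by limma (smallest adjusted p = 0.9996, median SE 0.085 log2 units), and 860 had an unadjusted p under 0.05. The log2 differences of the genes followed throughout were 0.42 ± 0.21 for Ccl2, 0.23 ± 0.24 for Il6, 0.12 ± 0.08 for Mmp3, 0.11 ± 0.14 for Il1b, 0.02 ± 0.39 for Hmox1, 0.02 ± 0.09 for Arg1 and −0.06 ± 0.09 for Tnf. These SEs came from the fit without a block, although the nodes of a rat correlated. They therefore do not measure the spread of the differences within rats. With rat as a fixed block 0 probe sets were called (smallest adjusted p = 0.6498 in limma) and 2150 had an unadjusted p under 0.05. With rat as a random block these were 0 (0.2306) and 1766, so the fit without a block was the more conservative. In data simulated for this comparison, limma recovered 58 of 67 probe sets changed 1.5-fold (86.6%) and 66 of 67 changed 2-fold (98.5%). The simulated values had no rat effect, and the 200 changed probe sets were drawn at random. With that many changed, by up to 4-fold, the Benjamini-Hochberg adjustment was milder than where few probe sets change. These rates therefore do not carry over to a few changes between the sides, or to genes with larger SEs, such as Hmox1, Il6 and Ccl2.

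Camera called 5 lists between the sides of the nodes although 0 of their members were called. The adipocyte genes (24 members, median −0.21; Adipoq −0.57 ± 0.28 and Pck1 −0.48 ± 0.26) and the synovial lining and fibroblast genes (27 members, median −0.10; Col1a1 −0.34 ± 0.16) lay lower on the bled side, both at a camera adjusted p of 1.5e-06 and at an adjusted p = 0.983 and adjusted p = 0.504 with an estimated correlation. The cell cycle genes had a median of −0.09 (camera adjusted p = 0.0108), the interferon-stimulated genes one of 0.08 (0.0258) and the immediate-early and heat-shock genes, among them Fos (0.28 ± 0.30), one of 0.08 (0.00587), each with adjusted p = 0.983 with an estimated correlation. In these 5 lists 0 members were called adjusted over the list alone.

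Nodes of the bled side were then compared with sham nodes. The leading increases were in the metallothionein gene Mt2A (1.80 ± 0.27, 3.49-fold, n = 11 and 9, adjusted p = 0.000786), the acute phase gene Serpina3n (1.76 ± 0.41, 3.39-fold), the lipase gene Lipg (1.75 ± 0.27), the secreted phospholipase gene Pla2g2a (1.65 ± 0.27), Vsig4 (1.61 ± 0.29), Sfrp4 (1.47), the chemokine gene Cxcl14 (1.41), Reg3g (1.396), Slc11a1 (1.33) and Timp1 (1.33). The decreases were smaller and began with Prg2, an eosinophil granule protein gene (−0.98 ± 0.21, 1.98-fold lower), Spon2 (−0.83), Foxred2 (−0.80), Dnmt3l (−0.77), Spo11 (−0.67), Trpm6 (−0.65), Or10aa3 (−0.61), Wif1 (−0.60), Col14a1 (−0.59) and Havcr1 (−0.58). Tnf fell by 0.32 ± 0.09 (adjusted p = 0.0431). Hmox1 (1.23 ± 0.41), Il6 (0.72 ± 0.25), Ccl2 (0.67 ± 0.22), Il1b (0.41 ± 0.15), Arg1 (0.14 ± 0.10) and Mmp3 (−0.05 ± 0.09) were not called, with adjusted p from 0.0825 to 0.804.

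Plasma cell and germinal centre genes rose in these nodes, 11 of 18 and none falling (14 adjusted over the list alone), with the endoplasmic reticulum gene Fkbp11 at 0.90 ± 0.16, Mzb1 at 0.80 ± 0.23, Derl3 at 0.79 ± 0.16 and Sdc1 at 0.75 ± 0.12 (camera adjusted p = 1.29e-11; adjusted p = 0.106 with an estimated correlation). Of 32 interferon-stimulated genes 9 rose, or 16 adjusted over the list alone, with Mx2 at 1.07 ± 0.27, Isg15 at 0.88 ± 0.23 and Ifit3 at 0.86 ± 0.22. The interferon-stimulated gene list had a camera adjusted p of 3.76e-09, and adjusted p = 0.235 with an estimated correlation. Of 24 oxidative stress genes 8 rose, or 12 adjusted over the list alone, including Mt1 (0.87 ± 0.18) and Nqo1 (0.79 ± 0.17). The oxidative stress gene list had a camera adjusted p of 8.76e-08, and adjusted p = 0.106 with an estimated correlation. Of 16 complement genes 5 rose, or 7 adjusted over the list alone, with the receptor gene C3ar1 at 1.28 ± 0.24, Cfb at 0.93 ± 0.13 and Serping1 at 0.48 ± 0.08. The complement gene list had a camera adjusted p of 5.27e-07, and adjusted p = 0.106 with an estimated correlation. Of 23 haem and iron handling genes 9 rose (13 rose and 1 fell adjusted over the list alone), including the haemoglobin scavenger receptor gene Cd163 (1.21 ± 0.29) and Lcn2 (0.89 ± 0.21). The haem and iron handling gene list had a camera adjusted p of 1.91e-06, and adjusted p = 0.106 with an estimated correlation.

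Of 25 monocyte and macrophage markers 8 rose (11 rose and 1 fell adjusted over the list alone), with Ccr2, a receptor of recruited monocytes, at 1.13 ± 0.22. The monocyte and macrophage marker list had a camera adjusted p of 1.29e-05, and adjusted p = 0.235 with an estimated correlation. Of 31 chemokine genes 9 rose (11 rose and 1 fell adjusted over the list alone), with Ccl7 at 1.05 ± 0.28 and the interferon-induced Cxcl10 at 0.73 ± 0.17. The chemokine gene list had a camera adjusted p of 0.000375, and adjusted p = 0.106 with an estimated correlation. Of 18 anti-inflammatory and feedback genes 3 rose, or 6 adjusted over the list alone, including Socs3 (0.94 ± 0.27) and the phosphatase gene Dusp1 (0.92 ± 0.22), which feeds back on stress kinases. The anti-inflammatory and feedback gene list had a camera adjusted p of 0.000208, and adjusted p = 0.106 with an estimated correlation. Adipocyte genes moved with this comparison: 3 of 24 rose (6 rose and 1 fell adjusted over the list alone), namely Lep (1.10 ± 0.33), Cidec (1.08 ± 0.30) and Pparg (0.75 ± 0.20), with a camera adjusted p of 0.000653 and adjusted p = 0.403 with an estimated correlation, and their mean was 8.03 ± 0.48 (SD, n = 11) on the bled side and 7.68 ± 0.39 (n = 9) in sham nodes.

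Between nodes of the bled side and sham nodes 1561 probe sets differed, 701 higher and 860 lower, or 938 and 414 with each array centred on its median, while 43 were at least 2-fold higher and 2 at least 2-fold lower. In all, 857 were called when only these groups were fitted, 926 without the sham arrays of C2 and C9 and 444 with the adipocyte mean as a covariate, of which 835, 733 and 434 were among the 1561. Without C2 and C9 the calls of Serpina3n, Sfrp4, Slc11a1, Trpm6, Socs3, Dusp1, Ccl7, Lcn2, Lep, Cidec, Pparg, Mx2, Isg15 and Mzb1 were lost, with median centring those of Or10aa3 and Tnf, and the adipocyte covariate ended those of Reg3g, Foxred2, Spo11, Cd163, Nqo1 and Ifit3, which the other fits named here had kept. Leaving out 1 array gave 803 calls without the sham array of C2 and 954 without the bled-side array of K11, and the calls of Lep and Tnf were lost on leaving out any 1 of 21 and 15 arrays.

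The contralateral nodes were likewise compared with sham nodes, which asked whether the side away from the bleed differed too. Serpina3n (1.83 ± 0.41, 3.56-fold, n = 11 and 9, adjusted p = 0.00919), Pla2g2a (1.77 ± 0.27, 3.42-fold), Vsig4 (1.77 ± 0.29), Lipg (1.65 ± 0.27), Sfrp4 (1.61), C3ar1 (1.57 ± 0.24), Cidec (1.51), Mt2A (1.45 ± 0.27), Lep (1.44) and the proteoglycan gene Vcan (1.396) led the increases. Prg2 (−0.95 ± 0.21, 1.93-fold lower), Foxred2 (−0.70), Spo11 (−0.69), Dnmt3l (−0.61), Rsrp1 (−0.60), Sstr3 (−0.58), Uhrf2 (−0.57), Adam11 (−0.56), Trpm6 (−0.55) and Wif1 (−0.55) led the decreases. None of the 7 genes followed throughout was called, Hmox1 being at 1.21 ± 0.41 (adjusted p = 0.0831), Il6 at 0.49 ± 0.25, Il1b at 0.30 ± 0.15, Ccl2 at 0.25 ± 0.22, Arg1 at 0.12 ± 0.10, Mmp3 at −0.17 ± 0.09 and Tnf at −0.26 ± 0.09 (adjusted p = 0.104).

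**Figure D4:**
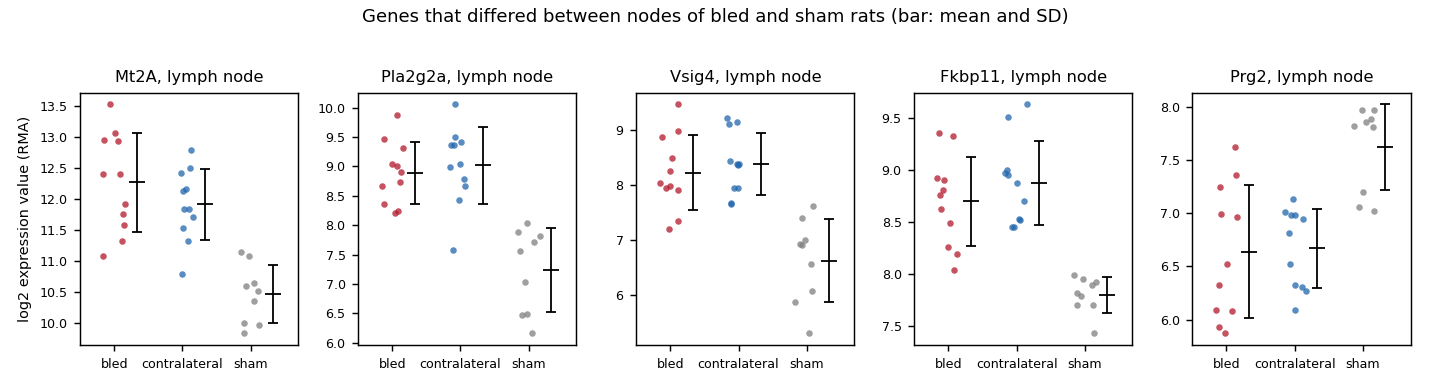
Log2 expression values of Mt2A, Pla2g2a, Vsig4, Fkbp11 and Prg2 in each lymph node array of the bled side, the contralateral side and the sham rats; each point is 1 array and the bar gives the mean and SD. Fkbp11 lay between 7.43 and 7.99 in sham nodes, below every array of the bled (8.04 to 9.35) and the contralateral side (8.45 to 9.63), and Prg2 between 7.02 and 7.97 in sham nodes and between 6.09 and 7.13 on the contralateral side; the value axes differ between panels.

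Of 18 plasma cell and germinal centre genes 13 rose and none fell in the contralateral nodes (15 adjusted over the list alone), with Fkbp11 at 1.07 ± 0.16, Mzb1 at 0.93 ± 0.23, Derl3 at 0.83 ± 0.16 and Sdc1 at 0.75 ± 0.12. The plasma cell and germinal centre gene list had a camera adjusted p of 3.76e-14, and adjusted p = 0.116 with an estimated correlation. Of 16 complement genes 5 rose, or 11 adjusted over the list alone, including Cfb (0.89 ± 0.13). The complement gene list had a camera adjusted p of 3.94e-08, and adjusted p = 0.116 with an estimated correlation. Of 25 monocyte and macrophage markers 9 rose, or 13 adjusted over the list alone, with Cd163 at 1.27 ± 0.29 and Ccr2 at 1.20 ± 0.22. The monocyte and macrophage marker list had a camera adjusted p of 5.84e-06, and adjusted p = 0.199 with an estimated correlation. Of 23 haem and iron handling genes 7 rose, or 11 adjusted over the list alone, with Slc11a1 at 1.26 ± 0.34. The haem and iron handling gene list had a camera adjusted p of 1.68e-06, and adjusted p = 0.116 with an estimated correlation. Of 31 chemokine genes 7 rose (10 rose and 1 fell adjusted over the list alone), with Cxcl14 at 1.28 ± 0.21 and Cxcl9 at 0.83 ± 0.19. The chemokine gene list had a camera adjusted p of 0.000908, and adjusted p = 0.116 with an estimated correlation. Of 32 interferon-stimulated genes 5 rose, or 9 adjusted over the list alone, with Oasl at 0.73 ± 0.22 and Irf7 at 0.66 ± 0.16. The interferon-stimulated gene list had a camera adjusted p of 3.38e-06, and adjusted p = 0.349 with an estimated correlation. Timp1, the gene of a metalloproteinase inhibitor, rose by 1.30 ± 0.25.

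Of 24 adipocyte genes 10 rose (16 rose and 1 fell adjusted over the list alone), including Pparg (1.06 ± 0.20) and Gpd1 (1.03 ± 0.29). The adipocyte gene list had a camera adjusted p of 3.94e-08, and adjusted p = 0.199 with an estimated correlation. Their mean was 8.25 ± 0.22 (SD, n = 11) in contralateral and 7.68 ± 0.39 (n = 9) in sham nodes. Of 27 synovial lining and fibroblast genes 7 rose (11 rose and 1 fell adjusted over the list alone), with the lubricin gene Prg4 at 0.94 ± 0.29. The synovial lining and fibroblast gene list had a camera adjusted p of 6.84e-07, and adjusted p = 0.116 with an estimated correlation.

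Between contralateral and sham nodes 1844 probe sets differed, 813 higher and 1031 lower, or 1052 and 442 with each array centred on its median, while 53 were at least 2-fold higher and 3 at least 2-fold lower. In all, 1137 were called when only these groups were fitted, 1063 without the sham arrays of C2 and C9 and 55 with the adipocyte mean as a covariate, of which 1086, 826 and 55 were among the 1844. Without C2 and C9 the calls of Dnmt3l, Adam11, Trpm6, Slc11a1, Prg4, Gpd1, Oasl and Irf7 were lost and with median centring those of Foxred2, Dnmt3l, Trpm6 and Wif1, while with the covariate the genes named here that stayed called were Pla2g2a, Lipg, C3ar1, Vcan, Fkbp11, Sdc1, Cfb and Irf7. Leaving out 1 array gave 941 calls without the sham array of C2, 1195 without the contralateral array of K11 and 1213 without that of K4, and the calls of Foxred2, Prg4 and Trpm6 were lost on leaving out any 1 of 22, 22 and 21 arrays.

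Whether the effects differed between knee and node was tested as a difference of differences. For the bled against the contralateral side 10206 probe sets differed between the tissues, 5675 with the higher effect in the knee and 4531 with the higher effect in the node. The difference was 5.93 ± 0.19 log2 units for Arg1 (adjusted p = 7.72e-34), 5.52 ± 0.32 for Il6, −5.35 ± 0.33 for Sult1a1 and −4.66 ± 0.37 for Omd. For the contralateral side against sham 746 probe sets differed between the tissues, 419 with the higher effect in the knee and 327 with the lower. The larger share turned to the lower side without the arrays of C5, C2 and C9 (480 in all, 217 higher and 263 lower), with array weights (243 and 276) and with quantile normalization (448 and 474). The knee effect exceeded that in the node by 1.402 ± 0.24 for Dbp and 1.13 ± 0.20 for Tef, whereas Vcan (−1.96 ± 0.33), Lipg (−1.65 ± 0.36), Bmal1 (−1.56 ± 0.25) and Npas2 (−1.51 ± 0.29) had the lower effect in the knee.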

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

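The tests of the clock genes, of fat in the nodes and of the sham arrays that stood apart were chosen only after the results they concern had been seen, whereas the differences between tissues and the splits of the arrays were planned.

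Single sham arrays lay far from the rest of their group by Dixon's test, which was run on the sham groups since the others held more than 10 arrays. It was exceeded by 5 of 74 values in the knee and 8 of 64 in the node, where chance gives about 1 in 20. In the sham knees, rat C1 had the lowest Pck1 (10.87, next 11.82), the highest Spp1 (11.26, next 7.45) and the lowest mean of the adipocyte genes (10.36, next 10.75), and C5 the lowest correlation with its group (0.9654, next 0.9843) and the highest array median (5.94, next 5.77). In the sham nodes, C9 had the lowest correlation with its group (0.9655, next 0.9838), the lowest Ccr2 (7.25, next 9.25), Derl3 (6.21, next 7.09), Nqo1 (5.17, next 5.94) and Timp1 (7.81, next 8.4) and the highest Mmp3 (5.53, next 5.11), and C1 the highest Ifit3 (6.64, next 5.87) and Mx2 (9.23, next 7.91).

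Knee and node differed both between the sides and between the contralateral side and sham, by a test of the difference itself. Between the bled and the contralateral side 10206 probe sets did so, with the knee effect minus the node effect at 5.93 for Arg1, 5.52 for Il6, 4.85 for Fgf23, 4.67 for Mmp13, 4.60 for Slpi and 4.57 for Clec4a2, and at −5.35 for Sult1a1, −4.66 for Omd, −4.43 for Tnfsf10, −4.21 for Cytl1, −4.13 for Myoc and −3.94 for Lgals12. Between the contralateral side and sham 746 did so, with 1.42 for Fam169b, 1.402 for Dbp, 1.13 for Tef, 1.11 for Nat8f3, 1.08 for Mthfd1l and 1.04 for Nox4, and −2.065 for Angptl4, −1.96 for Vcan, −1.945 for Aldh1l2, −1.65 for Lipg, −1.56 for Bmal1 and −1.51 for Npas2. Without the sham arrays that stood apart 480 were called, 396 of them among the 746, and the call of Angptl4 was lost (adjusted p = 0.0512).

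Among the named genes, the largest changes between contralateral and sham knees were in genes of the circadian clock. A score (the mean of Dbp, Tef, Nr1d1, Per1, Per2, Per3, Ciart, Cry2 and Bhlhe41 minus that of Bmal1, Npas2, Clock, Nfil3 and Cry1) was written after those genes had been seen. It was higher than in sham by 2.18 in contralateral knees (exact permutation p = 3.14e-05, the smallest possible). Its genes were chosen from this comparison, so that p is no test of the pattern. The difference was 2.14 without the sham array of C5 (p = 8.08e-05), and its size argues against that array alone as the cause. The score was also higher than in sham by 0.7 in contralateral nodes (exact permutation p = 4.17e-05) and by 0.65 in nodes of the bled side (p = 0.000107). The nodes came from the same rats as the knees, so both p values are no independent tests of the score, which was written after the data had been seen. In bled knees it lay 0.33 above sham (p = 0.0641), but as a mean over members that went both ways: of 9 called genes 5 moved with the score, among them Npas2 (−2.29), Bmal1 (−1.22), Clock (−0.49) and Dbp (0.84), and 4 against it, Nr1d1 (−1.23), Cry2 (−0.72), Nfil3 (1.28) and Cry1 (0.78). A response at the joint that bled therefore cannot be told apart from other causes in the bled knee, where the score was lower than in the contralateral knee of all 11 rats (mean change −1.86, sign-flip p = 0.000977, the smallest possible); that test was first read as arguing against such a response, before its members had been looked at. For the contralateral side a candidate explanation is tissue collected at another time of day in bled than in sham rats, while a response of the whole animal to the bleed went with the groups and was not tested. Neither collection times nor hybridization batches were given in the sources used here.

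Nodes of both sides differed from sham nodes. Part of the cause may lie in fat attached to the nodes, in the sham arrays of C2 and C9 or in another time of collection. Clock genes were among the calls: Bhlhe41 had the smallest limma adjusted p against sham on the bled side (3.67e-05) and the contralateral side (1.95e-05). Dbp, Tef, Nr1d1, Per2, Ciart and Bmal1 were also called on both sides, whereas Per1, Cry2, Npas2, Clock, Nfil3 and Cry1 were called on neither. The adipocyte mean was higher than in sham by 0.58 in contralateral nodes (exact permutation p = 0.000893) and by 0.35 in nodes of the bled side (p = 0.0936, not passed, although 1561 probe sets were called there). With it as a covariate 55 of 1844 calls were kept, while the called probe sets kept a median of 84.9% of their log2 fold change (median size 0.35 before and 0.29 after) and the median SE went from 0.087 to 0.101, so that calls ended through smaller folds and wider errors together. Without C2 and C9, 826 of the 1844 stayed called, and 1063 probe sets were called in all, which argues against these arrays as the whole cause. The 1844 kept 85.7% of their fold, all with the same sign. They had been chosen with C2 and C9 included and most arrays were shared, so this outcome was nearly set in advance. The rule first written asked only for the count, and by it these arrays would have counted as the cause. The condition on the folds was added after the count had been seen. For the 1844 probe sets of the contralateral nodes the parts of fat, these arrays, the time of collection and a response to the bleed cannot be told apart. The covariate and the arrays left out each ended calls while most of the fold stayed. Neither collection times nor hybridization batches were given in the sources used here, so a difference of batch between bled and sham rats was not tested either.

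Other splits of the same arrays into groups of the same sizes, 100 each with the real one, showed how often a random grouping gave as many calls. The real split alone gave its count (1 of 100) for bled against contralateral knees (12728, highest other 6065, or 10251 when sides were swapped within rats, again 1 of 100). So it did for bled against sham knees (14215 and 3506), contralateral against sham knees (666 and 374), nodes of the bled side against sham (1561 and 14) and contralateral nodes against sham (1844 and 112). The tissue differences also gave their counts alone (10206 and 7527, 746 and 251). With 100 splits, 1 of 100 is the finest share that can be shown, so chance was made unlikely for these counts but not excluded. For the 10206 the swaps moved both tissues of a rat together, so they mainly tested the knee effect again. For the sides of the nodes, where limma called 0 (860 at an unadjusted p under 0.05), all 100 splits and all 100 swaps within rats gave at least as many (at most 3 and 1), as any split must against a count of 0, so the splits say nothing about that comparison.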

How the results depend on the processing

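Leaving out arrays and the covariates were chosen after the results had been seen, while the other alternatives were planned. Counts of called probe sets, without the 2-fold minimum, moved by over 1.5 times in these cases only. Contralateral against sham knees (666) gave 381 with only the compared groups, 402 with array weights and 408 without C5, and 408 (C5) to 772 (C2) on leaving out each array. Nodes of the bled side against sham (1561) gave 857 with only the compared groups, 926 without C2 and C9 and 444 with the adipocyte covariate, and 803 (C2) to 2122 (C9) on leaving out each array. Contralateral nodes against sham (1844) gave 1137, 1063 and 55 in the same fits and 941 (C2) to 2378 (C9). The contralateral-to-sham difference between tissues (746) gave 480 without the arrays that stood apart. Counts with the 2-fold minimum moved as well. For contralateral against sham knees they went from 114 to 33 with 1 probe set per gene. That fit left out probe sets without a single symbol, and the reported fit itself held 18 genes at least 2-fold higher and 13 lower. Without C2 and C9 they went from 45 to 19 for nodes of the bled side and from 56 to 26 for contralateral nodes. The adipocyte covariate gave 24 and 12 there. Bled knees gave 12332 to 13457 calls against the contralateral and 13048 to 14397 against sham knees on leaving out each array, and the sides of the nodes 0.

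With rat as a replicate block the counts were 13818 (fixed) and 13150 (random) for the sides of the knees, 0 and 0 for those of the nodes, 14198 and 671 for bled and contralateral against sham knees, 1677 and 1958 for the nodes against sham, and 10467 (random), 11362 (per rat) and 965 for the tissue differences. Beside the chemokine and dendritic cell lists of the knee (adjusted p = 0.0814 and 0.0866), the block changed the calls of Pgk1 and Ndufb9 in nodes of the bled side against sham, which it added (adjusted p = 0.049 and 0.0499), and no other call of a named gene. Lists were run with the block only between the sides, where it changed no other list call. No named gene called in the reported fit or in an alternative changed its sign between these fits. Sign changes of genes called in neither fit were not counted. Of the alternative values of named genes, called or not, 1275 of 1276 gave the same outcome as the reported fit for the sides of the knees, 1184 of 1189 for bled against sham and 720 of 769 for contralateral against sham knees. For the sides of the nodes 297 of 297 did so, a share fixed in advance, since no fit called any probe set there. For the nodes against sham these were 799 of 930 and 802 of 909. Fry kept 19 of 19, 23 of 23, 8 of 15, 0 of 5, 18 of 20 and 12 of 19 list calls in that order, the estimated correlation 0, 0, 1, 0, 0 and 0, and leaving out the arrays that stood apart 16, 22, 13, 5, 17 and 15.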

Other observations

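The tests of the interferon-stimulated genes below were chosen only after their fall in the bled knee had been seen, while the list tests of the first paragraph were planned.

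Several lists not described so far held large single changes in the bled against the contralateral knee without passing as lists. Of 24 prostaglandin and pain mediator genes 10 rose and 5 fell, with the inducible nitric oxide synthase gene Nos2 at 3.38 ± 0.35 (10.4-fold) and Ptgs2 at 2.79 ± 0.21, each higher in 11 of 11 rats (camera adjusted p = 0.224). Of 16 peripheral nerve and Schwann cell genes 8 fell and 3 rose (4 adjusted over the list alone), with the glial gene S100b at −2.77 ± 0.18 in 11 of 11 rats (camera adjusted p = 0.101). Of 17 bone and osteoclast genes 4 rose and 5 fell, with the osteoclast receptor gene Oscar at 3.19 ± 0.18 and the phosphate-regulating gene Phex at −3.02 ± 0.18; their median was −0.157 while their mean was 0.128, and camera pointed downward (adjusted p = 0.755).

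Interferon-stimulated genes fell in the bled knee. Their mean fell by 0.73 log2 units per rat against the contralateral knee, in 11 of 11 rats (sign-flip p = 0.000977, the smallest possible). A raised level in the contralateral knee is argued against as the whole cause, since the mean was also lower in bled than in sham knees (−0.4, exact permutation p = 0.0231). It may be part of the cause, as the mean in contralateral knees lay 0.33 above sham (p = 0.0792), a difference that did not pass. Dilution of resident cells by arriving cells may be part of the cause, and this cannot be told apart from lower expression: the list fell by less than the adipocyte genes (difference 1.37), by more than the endothelial genes (−0.48, sign-flip p = 0.000977), and without a called difference from the fibroblast (−0.24, p = 0.0801) and cartilage genes (0.15, p = 0.277).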
